A study of Mus musculus with 20 samples.

How the data were processed

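Whole prostates from 20 mice in 4 groups of 5 (sham, castrated 3 days, castrated 14 days, and castrated 14 days followed by a testosterone pellet for 3 days) were measured on 1 array each. Samples were grouped from their labels, which named neither batches nor pairs. The running numbers in the array titles followed the groups. They were consecutive over sham and castrated 3 days, with a gap before castrated 14 days and another before the testosterone group. What the numbers stand for was not given, so a batch that follows the groups cannot be told apart from treatment. The deposited values are intensities: 1 signal per probe set on a linear scale, computed with MAS5 version 5.0 according to the submitters' processing notes. The mean of each array without the lowest and highest 2% of probe sets lay between 499.92 and 500.42, from which a scaling of each array before the values were deposited was inferred. The signals were not log transformed when deposited. Software and settings for scanning were not given in the sources used here. No more than 0.368% of probe sets had identical values on any pair of arrays, and the highest correlation between arrays was 0.981. Precision is limited by the number of arrays.

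The table held 12488 probe sets, of which 66 were Affymetrix controls and were left out of the tests. Of the other 12422, 10833 had 1 gene symbol, 396 several and 1193 none. Symbols came from the GEO annotation of the array, and 10817 probe sets with 1 Entrez ID were checked against a RefSeq gene table (assembly GRCm38.p6), which changed none. Values were analysed as log2 of the signal plus a pseudocount of 12.7, the 10th percentile of all values, without further normalization. Probe sets above 190.8, the median of all values, on at least 5 of 20 arrays were tested, which left 6913 (55.7%) and 5372 genes with a single symbol.

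All 4 groups entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes), with 5 contrasts, two-sided tests and Benjamini-Hochberg adjustment over the probe sets of each contrast, at a threshold of 0.05. Folds are 2 to the power of the log2 change. Log2 changes carry the standard error (SE) of the model, and signals are mean ± SD over 5 mice. Comparisons of array quality used exact permutation tests, for which 5 against 5 arrays give a smallest two-sided p of 0.00794. For each gene the probe set with the highest mean was used. The genes named were fixed by a rule before the data were examined: per comparison, the 12 with the largest rise and the 12 with the largest fall among those past the threshold, with 1 symbol, with no overlap between the groups' values and with the higher group's mean above 190.8; up to 4 members of each gene list with the largest change among those past the threshold; and a fixed set with Pbsn, Clu, Fkbp5, Mki67, Cdh13, Krt5, Krt8 and Acta2, the rest of which is not reported here. A selection of these is given, and Krt5 did not pass the filter. Members that moved against the rest of their list were also named, and these were chosen after their values were seen. Of 343 genes so named, 53 had more than 1 probe set tested, and for 1, Lcn2, another probe set was called in the opposite direction.

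Before the data were examined, 29 gene lists were fixed from general knowledge: prostate secretory products, seminal vesicle secretion genes, androgen-responsive genes, castration-induced regression genes, apoptosis regulators, cell cycle, polyamine metabolism, endoplasmic reticulum folding and secretory pathway, cholesterol and fatty acid synthesis, smooth muscle, fibroblast and extracellular matrix, stromal growth factors and developmental signals, macrophage and myeloid, lymphocyte, antigen presentation and interferon response, endothelial, basal epithelial, luminal epithelial, nerve and neuroendocrine, skeletal muscle, adipocyte, urothelium, epididymis and other male tract, erythroid and blood, immediate early and stress response, nucleolar and ribosome biogenesis, oxidative phosphorylation and citrate cycle, glutathione and antioxidant, and cadherins and catenins. Each was tested with camera (preset correlation 0.01) against the other genes, adjusted over 145 tests, and again with a correlation estimated from the residuals and with fry. Member counts are given over all probe sets tested and adjusted over the list alone. Overlaps between comparisons that share a group were set against the product of the list sizes and against splits of the shared group, and their correlations and covariances against 100 simulations of unchanged groups sharing the same arrays. In simulated data, with normal noise of each probe set's SD within groups and 200 of 6913 probe sets changed by a log2 of 0.5, 1 or 2, 86.3% to 89.3% of those changed by 1 were called over the 5 comparisons, 44.9% to 49.9% of those changed by 0.5, 97.4% to 98.5% of those changed by 2, and 4.16% to 5.76% of calls were false.

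Alternatives fixed in advance were a pseudocount of 1 or the 25th percentile, no filter or a filter on the mean, quantile normalization, each array centred on its median, only the 2 groups compared in the fit, eBayes with trend and robust settings, array weights, the 3' to 5' ratio of control probe sets as a covariate, each array left out in turn, a threshold of 0.01 for the counts of changed probe sets, other list tests and the mean over a gene's probe sets. After seeing the data, a fit without the 4 arrays of high Gapdh 3' to 5' ratio and a fit with the skeletal muscle score as a covariate were added. Tables were handled with the R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots drawn with matplotlib 3.10.9.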

Results

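Whole prostates of C57/B6 mice aged 10 to 12 weeks were profiled on 20 Affymetrix mouse arrays in 4 groups of 5 mice. The groups were sham-treated mice, mice killed 3 days after castration, mice killed 14 days after castration, and mice that received a 15 mg testosterone pellet 14 days after castration and were killed 3 days later (the testosterone group). The design asks which transcripts change as the prostate regresses without androgen and which change when it regrows. Signals on the 20 arrays ran from 0 to 28576, with array medians between 154 and 224. Sham arrays and arrays of mice castrated for 3 days correlated closely with each other (mean r across probe sets = 0.936, against 0.948 among sham arrays and 0.974 among the castrated arrays). The mean r with sham was 0.823 at 14 days of castration and 0.855 in the testosterone group, and probe sets are not independent replicates in these correlations. The first principal component held 36.0% of the variance and the second 26.1%. The number of arrays, 5 per group, limits the precision.

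On 4 arrays the control probe sets for Gapdh, a glycolytic enzyme, had a far higher signal at the 3' end than at the 5' end. The log2 ratio was 2.05 and 1.82 on replicates 4 and 5 of the mice castrated for 14 days, and 4.54 and 3.93 on replicates 2 and 5 of the testosterone group, against -0.53 to -0.08 on the other 16 arrays. For beta-actin the same 4 arrays had log2 ratios of 0.73, 0.80, 1.11 and 0.82, against 0.29 to 0.68 on the rest. Between groups the ratios of Gapdh, of beta-actin and their mean gave exact permutation p-values from 0.0873 to 0.889 over 15 two-sided tests, the lowest Benjamini-Hochberg adjusted value being 0.618. With 2 of 5 arrays affected in a group such tests have little power. The log2 Gapdh ratio differed by 1.81 between the testosterone group and sham (exact permutation p = 0.198). The tests therefore do not show that quality was alike, as no sham array and no array of mice castrated for 3 days was affected. Every count of changed probe sets per comparison is also given without these 4 arrays, a setting chosen after the data were seen.

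**Figure D1:**
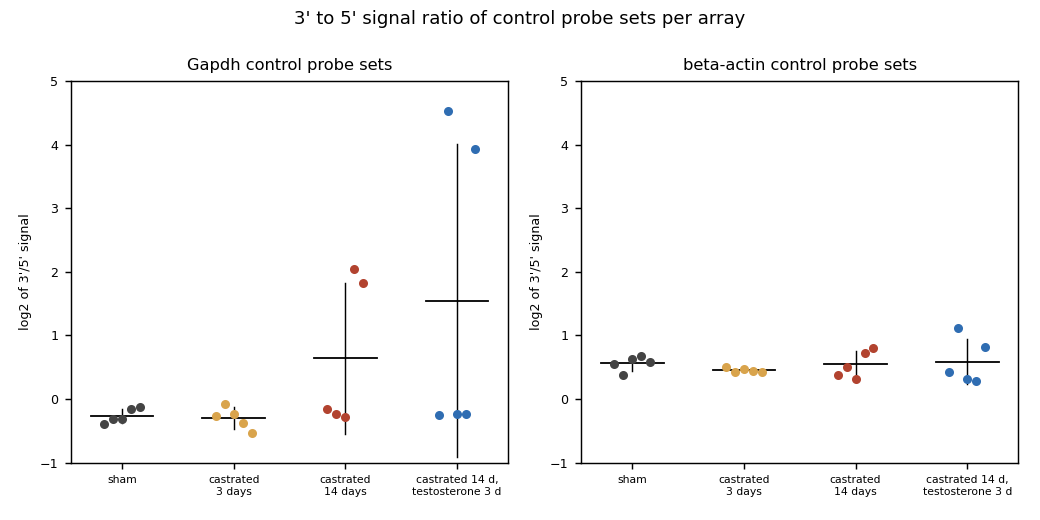
Log2 ratio of the 3' to the 5' signal of the Gapdh and beta-actin control probe sets on each of the 20 arrays, by group, with points for arrays, horizontal lines for means and vertical lines for SD. The Gapdh ratio exceeded 1 on 4 arrays, 2 from mice castrated for 14 days and 2 from the testosterone group.

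The comparison of castration for 3 days with sham addressed the early response to androgen loss. Msmb, a secreted prostate protein, fell 10.8-fold, from a signal of 10523 ± 1727 (SD, n = 5) to 1092 ± 582 (log2 change -3.43 ± 0.45 (SE), adjusted p = 5.4e-05). Cdo1, the enzyme that oxidises cysteine, fell 3.94-fold from 6663 ± 1647 to 1667 ± 298, and Cd52, a glycoprotein of leukocytes and of male tract epithelium, fell 4.88-fold. Ptgs2, a prostaglandin synthase, fell 3.99-fold. Higher signals were found for Dbp, a clock-controlled transcription factor (93.8 ± 59.0 in sham and 664 ± 119 after 3 days, log2 change 2.84 ± 0.28 (SE), adjusted p = 2.19e-06), and for Igfbp3, a binding protein for insulin-like growth factors (229 ± 44.4 and 1019 ± 441, log2 change 2.02 ± 0.23 (SE), adjusted p = 1.14e-05). The 5 arrays of a group lay apart from the 5 of the other for 13.3% of the probe sets tested against 0.794% by chance. Other large rises were those of Ccl8 (2.34), Ifit3 (2.24), Cadps (2.08), Slfn2 (1.85), Lama3 (1.70), Lsp1 (1.68), Tspan4 (1.68), Car8 (1.65) and Fos (1.59), given as log2 changes with adjusted p-values of 0.00694 or less. Large falls were those of Acta1 (-2.33), Pfkfb3 (-1.92), Bpgm (-1.78), Lct (-1.68), H2-Q10 (-1.67), Apof (-1.54) and Mthfd2 (-1.31), with adjusted p-values of 0.00333 or less. In all, limma called 680 probe sets higher and 308 lower of 6913 tested (Benjamini-Hochberg adjusted p under 0.05), of which 108 and 33 changed at least 2-fold. Without the 4 arrays of high Gapdh ratio the counts were 881 and 443. None of the 4 came from the groups compared here, but all groups share the estimate of the spread and the filter. With only the compared groups in the fit the counts were 702 and 324. With each array centred on its median they were 513 and 221, and 594 and 471 without a filter.

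Fkbp5, a co-chaperone of steroid signalling, fell from 1747 ± 521 to 902 ± 64.0 (log2 change -0.90 ± 0.15 (SE), adjusted p = 0.000478). Clu, the secreted chaperone clusterin, rose from 6035 ± 1633 to 10190 ± 1992 (log2 change 0.77 ± 0.17 (SE), adjusted p = 0.00413), and Cdh13, a cadherin anchored to the membrane by a lipid, rose from 26.0 ± 13.9 to 97.8 ± 42.1 (adjusted p = 0.00201). Its sham signals lay near the background, so the size of the change depends on the pseudocount added before the logarithm: the rise was 2.84-fold with 12.7, 2.00-fold with 43.2 and 3.77-fold with 1. Pbsn, the prostate secretory protein probasin, measured 16904 ± 1569 and 15179 ± 305 and did not pass the test (adjusted p = 0.441). Neither did the luminal keratin Krt8 (log2 change 0.37, adjusted p = 0.0787) nor the smooth muscle actin Acta2 (-0.12, adjusted p = 0.632).

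Genes of macrophages and other myeloid cells were higher after 3 days: 21 of 33 rose and 1 fell (26 and 1 adjusted over the list alone). The median was 0.77 (camera adjusted p = 8.36e-14, and adjusted p = 0.117 with an estimated correlation). They included Lsp1 and Tyrobp (1.52), a signalling adaptor of myeloid cells, while Cd52 was the member that fell. Of the antigen presentation and interferon genes, 17 of 32 rose and 0 fell (19 and 1 adjusted over the list alone), among them Ifit3, Iigp1 (1.51) and H2-DMb1 (1.48). Their median was 0.58 (camera adjusted p = 2.94e-09, and adjusted p = 0.138 with an estimated correlation). Of the fibroblast and matrix genes, 20 of 44 rose and 0 fell (27 and 0 adjusted over the list alone), led by Lum (1.47), Tcf21 (1.41) and Vcan (1.32). The median was 0.50 (camera adjusted p = 2.82e-10, and adjusted p = 0.121 with an estimated correlation). Genes linked in advance to prostate regression behaved likewise, in that 11 of 27 rose and 0 fell (11 and 0 adjusted over the list alone), including Plat (0.92) and Ndn (0.85). Their median was 0.32 (camera adjusted p = 0.000244, and adjusted p = 0.117 with an estimated correlation). Among genes of protein folding and transport in the endoplasmic reticulum, 0 of 60 rose and 15 fell (0 and 20 adjusted over the list alone), led by Herpud1 (-0.79) and Manf (-0.65), and the median was -0.30 (camera adjusted p = 2.46e-10, and adjusted p = 0.138 with an estimated correlation). Of the prostate secretory products, 0 of 15 rose and 3 fell (0 and 3 adjusted over the list alone), namely Msmb, Apof and Ang (-0.62). The median was -0.19 (camera adjusted p = 0.0074, and adjusted p = 0.138 with an estimated correlation).

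Skeletal muscle genes had a median log2 change of -0.67 with 1 of 30 members called, Acta1 (camera adjusted p = 0.00313, and adjusted p = 0.59 with an estimated correlation). A list of epididymal and other male tract genes with 4 measured members had 1 that fell, Defb2 (-1.39), a median of -0.33 and camera adjusted p = 0.0433, and adjusted p = 0.138 with an estimated correlation. Its call ended in 10 of 33 alternative settings, 7 of which left out 1 array, with adjusted p-values up to 0.119.

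After 14 days the contrast with sham was larger, and this comparison addressed the regressed gland. A single sham group served every contrast with sham. Its labels carried the code N3 without stating a time after surgery. In the codes C3 and C14 of the castrated groups the number was that of days after castration. Read in the same way, sham would match the 3-day group in time and not the later groups, but this was not established. Msmb reached 134 ± 95.3, 89.9-fold below sham (log2 change -6.49 ± 0.45 (SE), adjusted p = 1.09e-09). Fcgbp, a mucin-like protein that binds immunoglobulin, fell from 19768 ± 2502 to 1022 ± 518 (-4.39 ± 0.23 (SE), adjusted p = 2.97e-11), and Pbsn fell from 16904 ± 1569 to 4903 ± 854 (-1.80 ± 0.12 (SE), adjusted p = 4.67e-10). Igfbp3 rose 15.5-fold to 3764 ± 865 (3.96 ± 0.23 (SE), adjusted p = 1.35e-10), Cdh13 to 328 ± 90.3 (3.17 ± 0.30 (SE), adjusted p = 5.45e-08), and the major histocompatibility class II genes H2-Ab1 and H2-Aa 8.55-fold and 8.48-fold. Further rises were those of Cadps (3.69), Dbp (3.32), Car8 (3.23), Plxnd1 (3.14), Ccl5 (3.14) and Car3 (3.12), with adjusted p-values of 7.24e-05 or less, and further falls those of Ptgs2 (-3.44), Mcoln2 (-3.12), Traf1 (-2.89), Pdia4 (-3.00) and Trabd (-3.11), with adjusted p-values of 0.000729 or less. With pseudocounts of 43.2 and 1 (always in this order) the log2 changes were 2.41 and 3.71 for Cdh13, 2.42 and 3.64 for Plxnd1, 2.50 and 3.55 for Ccl5, -2.74 and -3.90 for Ptgs2, and -2.27 and -3.29 for Traf1. The 2 groups' arrays did not overlap for 35.0% of the probe sets tested. In all, limma called 1980 probe sets higher and 1679 lower of 6913 tested (Benjamini-Hochberg adjusted p under 0.05), of which 575 and 368 changed at least 2-fold. Without the 4 arrays of high Gapdh ratio the counts were 1708 and 1602. With each array centred on its median they were 1693 and 1745, and 2319 and 2690 without a filter.

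Fkbp5 was lower at 14 days (723 ± 93.7, log2 change -1.22 ± 0.15 (SE), adjusted p = 1.45e-06), while Clu (14572 ± 2238, 1.30 ± 0.17 (SE), adjusted p = 3.07e-06) and Krt8 (7107 ± 1539, 0.96 ± 0.14 (SE), adjusted p = 8.5e-06) were higher. Acta2 measured 4999 ± 815 in sham and 5476 ± 788 after 14 days and did not pass the test (adjusted p = 0.433). The secretory genes Svs6 (-4.34, or -3.53 and -5.15 with the other pseudocounts) and Sbp (-3.01) fell, with adjusted p-values of 0.000518 and 0.00345. Without sham replicate 1 the log2 change of Svs6 was -3.67, and without replicate 5 of the castrated mice that of Sbp was -1.98.

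Macrophage, antigen presentation, endothelial, nerve and fibroblast gene groups were higher than in sham. The lymphocyte list was not called: 7 of 10 rose and 1 fell (7 and 1 adjusted over the list alone), at a median of 1.41 (camera adjusted p = 0.0687). Of the macrophage and myeloid genes, 29 of 33 rose and 1 fell (30 and 1 adjusted over the list alone). Their median was 1.59 (camera adjusted p = 1.23e-12, and adjusted p = 0.117 with an estimated correlation), with Lgals3 (3.02), Aif1 (2.93) and Ctss (2.91) foremost and Cd52 (-1.33) again the member that fell. The other pseudocounts gave 2.30 and 3.34 for Aif1. In the antigen presentation and interferon list 29 of 32 rose and 1 fell (30 and 1 adjusted over the list alone). The median was 1.32 (camera adjusted p = 3.79e-12, and adjusted p = 0.121 with an estimated correlation), and the member that fell was B2m (-0.39), the light chain of class I molecules. Endothelial genes rose in part: 14 of 19 rose and 0 fell (15 and 1 adjusted over the list alone), including Cldn5 (1.96), Vwf (1.43) and Cdh5 (1.29). Their median was 0.78 (camera adjusted p = 0.00229, and adjusted p = 0.138 with an estimated correlation). Of nerve and neuroendocrine genes, 11 of 15 rose and 1 fell (11 and 1 adjusted over the list alone), including Snap25 (3.04), Prph (2.55) and Uchl1 (1.91). The median was 1.02 (camera adjusted p = 0.00487, and adjusted p = 0.24 with an estimated correlation), and the neurofilament gene Nefh (-1.42) fell. Snap25 had log2 changes of 2.30 and 3.76 with the other pseudocounts. Of fibroblast and matrix genes, 26 of 44 rose and 0 fell (26 and 0 adjusted over the list alone), led by Tcf21 (2.73), Lum (2.43) and Thy1 (2.27). Their median was 0.54 (camera adjusted p = 0.000217, and adjusted p = 0.267 with an estimated correlation). Of the regression-linked genes, 18 of 27 rose and 3 fell (18 and 3 adjusted over the list alone), led after Igfbp3 by Anxa1 (2.00) and Anxa2 (1.94), with Mmp7 (-0.89), Igfbp2 (-1.03) and Ctsd (-0.50) lower. The median was 0.67 (camera adjusted p = 0.000237, and adjusted p = 0.117 with an estimated correlation). The Ctsd call ended with quantile normalization (adjusted p = 0.132).

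Protein folding and secretion genes went the other way. In the endoplasmic reticulum list 0 of 60 rose and 50 fell (0 and 50 adjusted over the list alone), led by Pdia4 (-3.00), Creld2 (-2.34), Dnajc3 (-2.20) and Atf6 (-2.09). Their median was -0.74 (camera adjusted p = 4.62e-14, and adjusted p = 0.117 with an estimated correlation). All 5 measured seminal vesicle secretion genes fell, including Svs5 (-2.15) and Svs2 (-2.12). The median was -2.12 (camera adjusted p = 0.0173, and adjusted p = 0.267 with an estimated correlation). The mean log2 deviation of the list's genes ran from -3.57 to -0.43 over the castrated arrays. Whether their transcripts came from prostate cells was not tested. The Svs2 change was -0.97 without replicate 5 of the castrated mice, and its call ended with only the 2 groups in the fit (adjusted p = 0.0921). Of the prostate secretory products, 3 of 15 rose and 8 fell (4 and 8 adjusted over the list alone), with Mme (-2.65) among the lower and Lcn2 (1.80), Wfdc2 (1.68) and Mfge8 (0.37) the higher. Their median was -0.56 (camera adjusted p = 0.0283, and adjusted p = 0.198 with an estimated correlation). That call ended with quantile normalization, with array weights, without replicate 5 of the castrated mice and without the 4 arrays of high Gapdh ratio, at adjusted p-values from 0.0666 to 0.0753. Of its higher members, calls ended for Lcn2 in 5 of 33 settings, 2 of them leaving out 1 array (adjusted p up to 0.112) and Mfge8 in 7 of 33 settings, 5 of them leaving out 1 array (adjusted p up to 0.084), and the log2 change of Lcn2 was 2.64 without replicate 5 of the castrated mice. Another probe set of Lcn2 was called in the opposite direction.

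Growth factor and developmental signal genes moved in both directions, as 19 of 36 rose and 5 fell (20 and 5 adjusted over the list alone): Smo (2.21), Cxcl12 (2.04) and Kitl (1.52) rose while Egf (-2.60), Bmp7 (-1.49), Notch4 (-1.49), Fgf1 (-1.10) and Hoxb13 (-0.83) fell. The median was 0.59 (camera adjusted p = 0.0358, and adjusted p = 0.27 with an estimated correlation). The call ended with a filter on the mean signal (adjusted p = 0.0742) and, in a setting chosen after seeing the data, with the mean score of the skeletal muscle list as a covariate (0.0526). Of the oxidative phosphorylation and citrate cycle genes, 30 of 69 rose and 7 fell (32 and 7 adjusted over the list alone), including Idh1 (1.44) and Idh3a (0.92). Their median was 0.22 (camera adjusted p = 0.0283, and adjusted p = 0.512 with an estimated correlation), a call that ended with each array centred on its median (adjusted p = 0.0613) and with the muscle score (0.0509). In the male tract list 3 of 4 members fell, Defb2 (-1.99), Tnp1 (-0.79) and Odf1 (-0.62). The median was -0.71 (camera adjusted p = 0.0488, and adjusted p = 0.138 with an estimated correlation), and this call ended in 17 of 33 alternative settings, 8 of them leaving out 1 array, with adjusted p-values up to 0.112. Smooth muscle genes were not called: 8 of 20 rose and 5 fell (8 and 5 adjusted over the list alone), the median log2 change was 0.14, and camera pointed lower (adjusted p = 0.93).

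**Figure D2:**
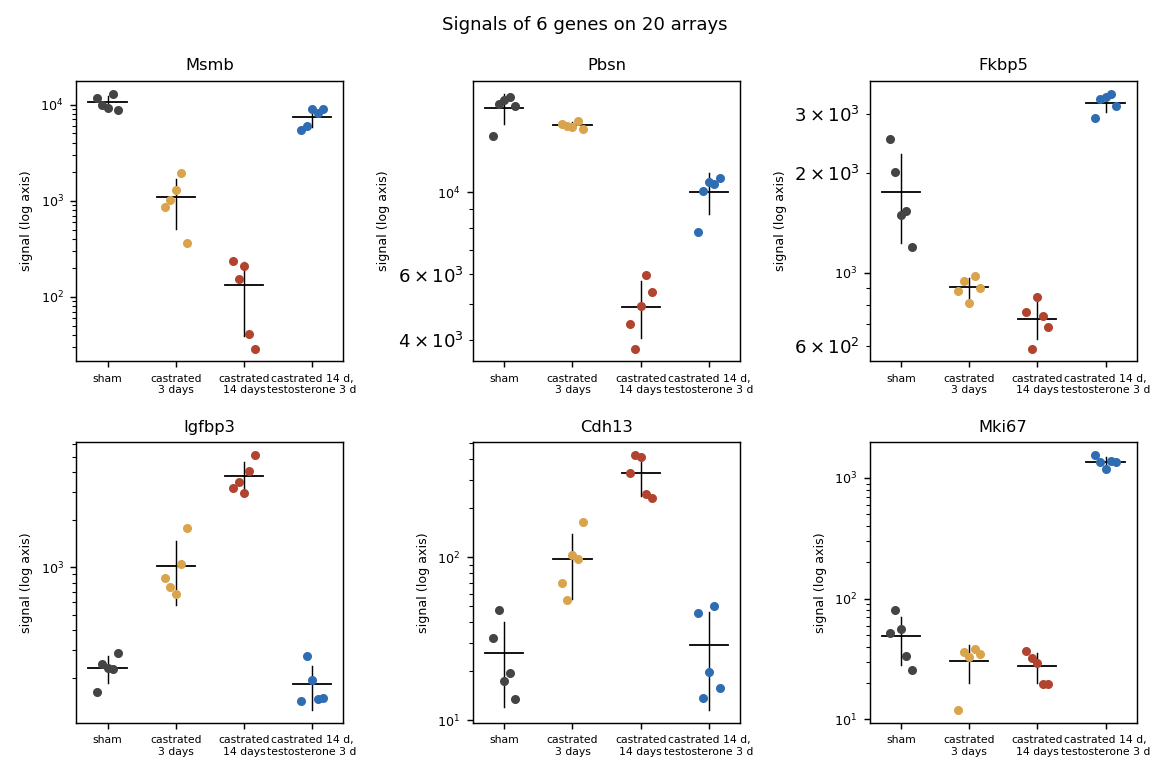
Signal of 6 genes on 20 arrays by group on a logarithmic axis, in arbitrary units, with points for arrays, horizontal lines for group means and vertical lines for SD (drawn down to 5% of the mean where they would fall below it). Msmb averaged 10523 in sham and 134 after 14 days of castration, and Mki67 averaged 1367 in the testosterone group.

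Between 3 and 14 days of castration, Fcgbp dropped from 18770 ± 1819 to 1022 ± 518 (log2 change -4.32 ± 0.23 (SE), adjusted p = 7.74e-11), Pbsn from 15179 ± 305 to 4903 ± 854 (-1.65 ± 0.12 (SE), adjusted p = 5.83e-09), and Azgp1, a secreted glycoprotein, 6.52-fold. Agr2 (-2.76), Msmb (-3.06), Traf1 (-2.79), Mcoln2 (-2.67) and Myh9 (-2.76) were also lower, with adjusted p-values of 0.000136 or less. Ccl5, a chemokine, rose from 33.6 ± 14.4 to 400.3 ± 54.6 (3.20 ± 0.32 (SE), adjusted p = 6.27e-07), and Cdh13 from 97.8 ± 42.1 to 328 ± 90.3 (1.66 ± 0.30 (SE), adjusted p = 0.00025). The other pseudocounts gave 2.54 and 3.62 for Ccl5, and -2.18 and -3.18 for Traf1. Krt8 rose from 4635 ± 562 to 7107 ± 1539 (0.60 ± 0.14 (SE), adjusted p = 0.00191). The rise of Clu (log2 change 0.53, adjusted p = 0.0175) was no longer past the threshold without replicate 4 of either group (adjusted p = 0.0589 and 0.0526) or without the 4 arrays of high Gapdh ratio (0.0927). Fkbp5 had a log2 change of -0.32 (adjusted p = 0.0897). In all, limma called 1395 probe sets higher and 1407 lower of 6913 tested (Benjamini-Hochberg adjusted p under 0.05), of which 266 and 244 changed at least 2-fold. Without the 4 arrays of high Gapdh ratio the counts were 1125 and 1295. With each array centred on its median they were 1069 and 1447.

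Macrophage and myeloid genes rose further (23 of 33 rose and 0 fell (25 and 0 adjusted over the list alone), median 0.81, camera adjusted p = 1.35e-09, and adjusted p = 0.121 with an estimated correlation), as did antigen presentation and interferon genes (25 of 32 rose and 0 fell (26 and 0 adjusted over the list alone), median 0.72, camera adjusted p = 1.95e-10, and adjusted p = 0.138 with an estimated correlation), with Cyba (1.60) and H2-Eb1 (2.44) among them. Of endothelial genes, 9 of 19 rose and 0 fell (10 and 0 adjusted over the list alone), including Cldn5 (1.62) and Nrp1 (1.27). Their median was 0.40 (camera adjusted p = 0.00094, and adjusted p = 0.138 with an estimated correlation). Of nerve and neuroendocrine genes, 9 of 15 rose and 0 fell (9 and 0 adjusted over the list alone), including Snap25 (2.24) and Prph (1.82). The median was 0.54 (camera adjusted p = 0.00318, and adjusted p = 0.213 with an estimated correlation). Of regression-linked genes, 15 of 27 rose and 2 fell (15 and 2 adjusted over the list alone), with Igfbp3 (1.93) and Anxa1 (1.90) higher. Their median was 0.33 (camera adjusted p = 0.00596, and adjusted p = 0.138 with an estimated correlation). Of oxidative phosphorylation and citrate cycle genes, 30 of 69 rose and 5 fell (36 and 5 adjusted over the list alone), including Slc25a4 (0.82) and Ndufa5 (0.75), with Slc25a1 (-1.37), the citrate carrier, among those that fell. The median was 0.27 (camera adjusted p = 0.000203, and adjusted p = 0.27 with an estimated correlation). In the endoplasmic reticulum list 1 of 60 rose and 37 fell (2 and 41 adjusted over the list alone), with Pdia4 (-2.31) and P4hb (-1.60) lower. Their median was -0.47 (camera adjusted p = 4.55e-10, and adjusted p = 0.138 with an estimated correlation).

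Prostate secretory products were not called as a list: 4 of 15 rose and 6 fell (5 and 7 adjusted over the list alone), at a median of -0.65 (camera adjusted p = 0.17). Seminal vesicle secretion genes fell in 4 of 5 cases, including Svs5 (-1.85) and Svs4 (-1.33). The median was -1.85 (camera adjusted p = 0.0263, and adjusted p = 0.27 with an estimated correlation), a call that ended with only the 2 groups in the fit (adjusted p = 0.0691) and with array weights (0.0703). The fall of Svs2 (-2.01) was -0.85 without replicate 5 of the castrated 14-day mice. Its call ended in 9 of 33 settings, 5 of them leaving out 1 array (limma adjusted p up to 0.116). Of lymphocyte genes, 6 of 10 rose and 2 fell (7 and 2 adjusted over the list alone), including Ltb (1.18) and Ighm (1.55). Their median was 1.10 (camera adjusted p = 0.0428, and adjusted p = 0.138 with an estimated correlation), and the call ended in 13 of 33 alternative settings, among them without any 1 of the castrated 14-day arrays, with adjusted p-values up to 0.317. Skeletal muscle genes were higher at 14 than at 3 days: 18 of 30 rose and 1 fell (22 and 1 adjusted over the list alone), including the cytochrome oxidase subunit gene Cox6a2 (3.59). The median was 1.91 (camera adjusted p = 0.00247, and adjusted p = 0.583 with an estimated correlation), and Myog (-1.66) fell. Their score, the mean log2 deviation of the list's genes, varied between arrays of one group, with an SD within groups of 0.956 against a median of 0.120 over the other 28 lists.

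Testosterone given for 3 days to mice castrated for 14 days addressed regrowth, and proliferation genes were among the largest rises. Mki67, a marker of dividing cells, rose from 27.7 ± 7.78 to 1367 ± 126 (log2 change 5.11 ± 0.22 (SE), adjusted p = 3.09e-12). Top2a (4.43), Kif20a (4.38), Cdk1 (4.34), Ckap2 (4.32), Nusap1 (3.85), Pclaf (3.74), Birc5 (3.74) and Cdc20 (3.60) rose too, with adjusted p-values of 9.21e-08 or less. Msmb rose 63.4-fold to 7497 ± 1698 (5.99 ± 0.45 (SE), adjusted p = 4.04e-09) and Fcgbp 17.9-fold to 16818 ± 1469. Fkbp5 rose to 3246 ± 207 (2.15 ± 0.15 (SE), adjusted p = 1.2e-09) and Pbsn to 10013 ± 1268 (1.04 ± 0.12 (SE), adjusted p = 7.31e-07). Igfbp3 fell 19.7-fold to 181 ± 56.6 (-4.30 ± 0.23 (SE), adjusted p = 5.13e-11) and Cdh13 fell to 29.1 ± 17.5 (-3.09 ± 0.30 (SE), adjusted p = 1.03e-07). Other large falls were those of Car8 (-3.73), Cadps (-3.68), Nupr1 (-3.56), Retn (-3.18), Car3 (-3.01), Apod (-2.89), Cxadr (-2.81) and Adipoq (-2.78), with adjusted p-values of 0.000127 or less. Signals near the background made the size of some changes depend on the pseudocount, as the 2 others gave 4.32 and 5.62 for Mki67, 3.51 and 5.14 for Top2a, 3.46 and 4.93 for Ckap2, 3.12 and 4.09 for Birc5, -2.36 and -3.61 for Cdh13, and -2.55 and -3.59 for Retn. Clu had a log2 change of -0.17 and did not pass (adjusted p = 0.433). The testosterone group was killed 3 days later after castration than the group it was compared with, and a castrated group of that time without hormone was not analysed here.

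In all, limma called 1259 probe sets higher and 1840 lower of 6913 tested (Benjamini-Hochberg adjusted p under 0.05), of which 300 and 398 changed at least 2-fold. Without the 4 arrays of high Gapdh ratio the counts were 1164 and 1482. The share of calls that were higher was 40.6%, against 64.1% (1827 higher and 1024 lower) with each array centred on its median, which moved the log2 changes by 0.20, so list medians are given both as deposited and centred. Quantile normalization moved them by 0.11. Krt8 (-0.54, adjusted p = 0.0031) lost its call when arrays were centred (adjusted p = 0.105) and without the 4 arrays of high Gapdh ratio (0.0573), and the rise of Acta2 (0.58, adjusted p = 0.00217) lost it with quantile normalization (0.0631).

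Of 54 cell cycle genes, 53 rose and 0 fell (53 and 0 adjusted over the list alone), with a median log2 change of 2.04 (2.24 centred), a camera adjusted p of 4.08e-38 and an adjusted p of 3.03e-05 with an estimated correlation. Of the 57 list calls in the 5 comparisons, 2 held with an estimated correlation, those of the cell cycle list here and against sham. Among cholesterol and fatty acid synthesis genes, 17 of 25 rose and 1 fell (17 and 1 adjusted over the list alone), including Idi1 (2.52), Mvd (2.46) and Sqle (1.91). Their median was 0.56 (0.75 centred) (camera adjusted p = 2.87e-06, and adjusted p = 0.117 with an estimated correlation), and Thrsp (-1.32), a regulator of lipid synthesis, fell. In the endoplasmic reticulum list 39 of 60 rose and 3 fell (41 and 3 adjusted over the list alone), including Creld2 (2.09), Pdia4 (2.01) and Kdelr3 (1.96). The median was 0.59 (0.79 centred) (camera adjusted p = 3.54e-12, and adjusted p = 0.121 with an estimated correlation), while Ddit3 (-1.59), Xbp1 (-0.58) and Canx (-0.41) fell. The call ended for Canx in 4 of 33 settings (adjusted p up to 0.221). Of the prostate secretory products, 8 of 15 rose and 1 fell (8 and 1 adjusted over the list alone), including Apof (3.53) and Mme (3.42, or 2.81 and 3.92 with the other pseudocounts). Their median was 0.61 (0.80 centred) (camera adjusted p = 0.00318, and adjusted p = 0.138 with an estimated correlation), and Aoc1 (-0.87) fell.

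Macrophage, antigen presentation and nerve gene groups fell. Of macrophage and myeloid genes, 1 of 33 rose and 28 fell (1 and 28 adjusted over the list alone), including Abca1 (-2.21), Mpeg1 (-2.13) and Aif1 (-1.95). The median was -0.91 (-0.71 centred) (camera adjusted p = 2.31e-07, and adjusted p = 0.138 with an estimated correlation), and Cd52 (2.03) rose. In the antigen presentation and interferon list 1 of 32 rose and 26 fell (1 and 26 adjusted over the list alone), including Ifit3 (-2.55) and H2-Eb1 (-2.55). Their median was -0.75 (-0.56 centred) (camera adjusted p = 9.63e-07, and adjusted p = 0.193 with an estimated correlation), and B2m (0.29) rose. Of nerve and neuroendocrine genes, 0 of 15 rose and 11 fell (1 and 11 adjusted over the list alone), including Snap25 (-2.89, or -2.20 and -3.52 with the other pseudocounts). The median was -0.62 (-0.42 centred) (camera adjusted p = 0.00645, and adjusted p = 0.254 with an estimated correlation). Of the growth factor and developmental signal genes, 3 of 36 rose and 20 fell (3 and 21 adjusted over the list alone), with Dkk3 (-1.67) and Sfrp1 (-1.42) lower and Bmp7 (1.11), Fst (0.75) and Hoxb13 (0.57) higher. Their median was -0.55 (-0.35 centred) (camera adjusted p = 0.00702, and adjusted p = 0.186 with an estimated correlation). Of the immediate early and stress genes, 4 of 41 rose and 21 fell (4 and 22 adjusted over the list alone), including Jun (-1.92) and Fos (-1.68). The median was -0.46 (-0.26 centred) (camera adjusted p = 0.0294, and adjusted p = 0.267 with an estimated correlation), and the 4 that rose were the metallothioneins Mt1 (1.66) and Mt2 (1.76) with Gadd45g (1.30) and Hsp90aa1 (0.67). Calls of members that rose ended for B2m in 10 of 33 settings, 5 of them leaving out 1 array (adjusted p up to 0.21), Fst in 1 of 33 settings (adjusted p = 0.0805), Hoxb13 in 5 of 33 settings, 4 of them leaving out 1 array (adjusted p up to 0.0934) and Hsp90aa1 in 2 of 33 settings (adjusted p up to 0.101).

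Of the remaining list calls in this comparison, that of the nucleolar and ribosome biogenesis genes was kept in all 33 settings run at the threshold of 0.05, other list tests aside, and the others were not. Of regression-linked genes, 1 of 27 rose and 13 fell (1 and 13 adjusted over the list alone), with Sparcl1 (-1.71) lower and Igfbp2 (1.13) higher. Their median was -0.32 (-0.12 centred) (camera adjusted p = 0.0329, and adjusted p = 0.254 with an estimated correlation), and the call ended without replicate 5 of the testosterone group (adjusted p = 0.0517). Of apoptosis regulators, 1 of 23 rose and 9 fell (1 and 12 adjusted over the list alone). The median was -0.38 (-0.19 centred) (camera adjusted p = 0.0281, and adjusted p = 0.138 with an estimated correlation), and the call ended with quantile normalization (adjusted p = 0.0728) and without the 4 arrays of high Gapdh ratio (adjusted p = 0.104). Bid (-1.56), Bcl2l11 (-1.35) and Bik (-1.31) were among the members that fell and Bak1 (0.46) was the one that rose. Of polyamine metabolism genes, 4 of 8 rose and 1 fell (4 and 1 adjusted over the list alone), with Odc1 (1.34) and Srm (1.52) higher and Sat1 (-0.91) lower. Their median was 0.64 (0.84 centred) (camera adjusted p = 0.0329, and adjusted p = 0.138 with an estimated correlation), and the call ended without a filter (adjusted p = 0.0553), with quantile normalization (adjusted p = 0.0954), with each array centred (adjusted p = 0.0613), with array weights (adjusted p = 0.055), with the 3' to 5' ratio as a covariate (adjusted p = 0.0729) and without the 4 arrays of high Gapdh ratio (adjusted p = 0.0782). Of smooth muscle genes, 10 of 20 rose and 2 fell (10 and 2 adjusted over the list alone), with Actg2 (2.93) the largest rise and Sncg (-0.91, adjusted p = 0.0699 without the 4 arrays of high Gapdh ratio) and Cav1 (-0.44) lower. The median was 0.33 (0.52 centred) (camera adjusted p = 0.018, and adjusted p = 0.385 with an estimated correlation), and the call ended without a filter (adjusted p = 0.0509), with quantile normalization (adjusted p = 0.155) and without the 4 arrays of high Gapdh ratio (adjusted p = 0.0578). The call of Cav1 ended with each array centred (adjusted p = 0.138). Of endothelial genes, 0 of 19 rose and 11 fell (0 and 12 adjusted over the list alone). Their median was -0.59 (-0.40 centred) (camera adjusted p = 0.0294, and adjusted p = 0.267 with an estimated correlation), and the call ended with a filter on the mean signal (adjusted p = 0.0839) and without the 4 arrays of high Gapdh ratio (adjusted p = 0.0578).

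Of lymphocyte genes, 1 of 10 rose and 7 fell (1 and 7 adjusted over the list alone), with Ccl5 (-2.44) and Ltb (-1.95) lower and Ms4a1 (0.51) higher. The median was -1.50 (-1.31 centred) (camera adjusted p = 0.0329, and adjusted p = 0.138 with an estimated correlation), and the call ended in 7 of 33 settings, 5 of them without 1 castrated 14-day array, with adjusted p-values up to 0.198. Of cadherins and catenins, 0 of 11 rose and 8 fell (0 and 8 adjusted over the list alone), with Dsc2 (-1.24) lower beside Cdh13. Their median was -0.43 (-0.23 centred) (camera adjusted p = 0.00656, and adjusted p = 0.117 with an estimated correlation), and the call ended without the 4 arrays of high Gapdh ratio (adjusted p = 0.0538). Of oxidative phosphorylation and citrate cycle genes, 24 of 69 rose and 3 fell (24 and 3 adjusted over the list alone), with Uqcrq (0.99) higher and Idh1 (-1.27), Ndufa6 (-0.73) and Sdha (-0.45) lower. The median was 0.24 (0.43 centred) (camera adjusted p = 0.000283, and adjusted p = 0.282 with an estimated correlation), and the call ended with quantile normalization (0.0712). Calls of single genes ended for Ms4a1 in 4 of 33 settings, 2 of them leaving out 1 array (adjusted p up to 0.158) and Sdha in 1 of 33 settings (adjusted p = 0.0788). Of seminal vesicle secretion genes, 4 of 5 rose and 0 fell (5 and 0 adjusted over the list alone), with Svs5 (1.68) higher. Their median was 1.68 (1.87 centred) (camera adjusted p = 0.0283, and adjusted p = 0.27 with an estimated correlation), and the call ended with quantile normalization (adjusted p = 0.0612), with each array centred (adjusted p = 0.0572) and with array weights (adjusted p = 0.0564). The rise of Svs2 (1.94) was 0.79 without replicate 5 of the castrated 14-day mice. Its call ended in 9 of 33 settings, 5 of them leaving out 1 array (limma adjusted p up to 0.146). Nucleolar and ribosome biogenesis genes (16 of 57 rose and 3 fell (15 and 3 adjusted over the list alone), median 0.09 (0.29 centred), camera adjusted p = 0.0128, and adjusted p = 0.267 with an estimated correlation) included Ran (0.90) and Nhp2 (0.71) among those that rose.

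The testosterone group was also set against sham, to see how far regrowing glands lay from intact ones. Proliferation genes were again among the largest rises: Mki67 (49.5 ± 21.5 in sham, log2 change 4.54 ± 0.22 (SE), adjusted p = 1.42e-11), with Stmn1 (3.67), Cdc20 (3.50), Cdk1 (3.81), Top2a (3.45), Tcf19 (3.40), Mcm5 (3.36) and Smc2 (3.34) at adjusted p-values of 2.39e-07 or less. Fkbp5 stood above sham (0.93 ± 0.15 (SE), adjusted p = 3.89e-05) and Pbsn below it (-0.76 ± 0.12 (SE), adjusted p = 2.76e-05), and Clu remained higher than in sham (1.13 ± 0.17 (SE), adjusted p = 2.02e-05), while Cdh13 measured 26.0 ± 13.9 in sham and 29.1 ± 17.5 with testosterone (log2 change 0.08, adjusted p = 0.837). Egf, the epidermal growth factor, fell 6.31-fold (6658 ± 1220.5 to 1041 ± 185, -2.66 ± 0.28 (SE), adjusted p = 4.03e-07), and Ptgs2 (-2.96), Omp (-2.44), Slc10a6 (-1.96), Fut9 (-1.95) and Nefh (-1.93) were lower too, with adjusted p-values of 1.86e-05 or less. The other pseudocounts gave -1.81 and -2.88 for Omp. Acta2 was higher (0.71, adjusted p = 0.000314), and Krt8 (0.43, adjusted p = 0.013) was past the threshold until the 3' to 5' ratio entered as a covariate (0.0554).

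In all, limma called 1624 probe sets higher and 2041 lower of 6913 tested (Benjamini-Hochberg adjusted p under 0.05), of which 401 and 295 changed at least 2-fold. Without the 4 arrays of high Gapdh ratio the counts were 1409 and 1710. They were 1763 and 3317 without a filter. The share of calls that were higher was 44.3%, and 62.7% (2026 higher and 1206 lower) with each array centred on its median, a shift of 0.17 in the log2 changes. Of 54 cell cycle genes 53 rose and 0 fell (53 and 0 adjusted over the list alone), at a median of 2.25 (2.42 centred), a camera adjusted p of 8.37e-34 and an adjusted p of 3.55e-05 with an estimated correlation. Of cholesterol and fatty acid synthesis genes, 17 of 25 rose and 0 fell (17 and 0 adjusted over the list alone), including Idi1 (3.08), Fdps (1.66) and Hmgcs1 (1.59). Their median was 0.65 (0.82 centred) (camera adjusted p = 1.77e-06, and adjusted p = 0.117 with an estimated correlation). Of fibroblast and matrix genes, 28 of 44 rose and 3 fell (28 and 3 adjusted over the list alone), including Col5a2 (2.73) and Col3a1 (2.35). The median was 0.64 (0.81 centred) (camera adjusted p = 2.31e-07, and adjusted p = 0.138 with an estimated correlation), and Dcn (-0.31), Fn1 (-0.29) and Gpc3 (-0.40) fell. Calls of these 3 genes ended for Dcn in 10 of 33 settings, 6 of them leaving out 1 array (adjusted p up to 0.433), Fn1 in 1 of 33 settings (adjusted p = 0.31) and Gpc3 in 13 of 33 settings, 6 of them leaving out 1 array (adjusted p up to 0.422). Of oxidative phosphorylation and citrate cycle genes, 45 of 69 rose and 4 fell (46 and 4 adjusted over the list alone), including Atp5o (1.34) and Ndufc1 (1.31). Their median was 0.43 (0.59 centred) (camera adjusted p = 1.42e-08, and adjusted p = 0.138 with an estimated correlation).

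Macrophage and antigen presentation genes stayed above sham, and lymphocyte genes were not called: 2 of 10 rose and 1 fell (0 and 0 adjusted over the list alone), at a median of -0.15 (0.02 centred) (camera adjusted p = 0.976). Of macrophage and myeloid genes, 23 of 33 rose and 4 fell (23 and 4 adjusted over the list alone), including Cd53 (1.98), Ccl8 (1.76) and Tyrobp (1.72). The median was 0.93 (1.10 centred) (camera adjusted p = 3.14e-05, and adjusted p = 0.202 with an estimated correlation), and Csf3r (-1.15), Abca1 (-0.86), Lcp1 (-0.35) and Itgax (-0.34) fell. Of antigen presentation and interferon genes, 20 of 32 rose and 1 fell (20 and 2 adjusted over the list alone), including H2-DMb1 (1.74) and Ifi204 (1.57). Their median was 0.54 (0.70 centred) (camera adjusted p = 0.000203, and adjusted p = 0.276 with an estimated correlation), and Irf8 (-0.39) fell. Calls of members that fell ended for Lcp1 in 3 of 33 settings, 1 of them leaving out 1 array (adjusted p up to 0.29), Itgax in 11 of 33 settings, 5 of them leaving out 1 array (adjusted p up to 0.348) and Irf8 in 2 of 33 settings (adjusted p up to 0.244). Of smooth muscle genes, 9 of 20 rose and 1 fell (9 and 1 adjusted over the list alone), with Actg2 (1.77) and Tpm1 (1.16) higher and Itga7 (-0.40) lower. The median was 0.31 (0.48 centred) (camera adjusted p = 0.0266, and adjusted p = 0.413 with an estimated correlation), and the call ended with quantile normalization (adjusted p = 0.0728) and with the mean over all probe sets of a gene (0.0502). Of nucleolar and ribosome biogenesis genes, 24 of 57 rose and 6 fell (24 and 7 adjusted over the list alone), with Nap1l1 (1.31) and Ran (1.21) among those that rose. Their median was 0.23 (0.40 centred) (camera adjusted p = 0.0283, and adjusted p = 0.314 with an estimated correlation), and the call ended with the mean over probe sets (0.0538). The call ended for Itga7 in 19 of 33 settings, 12 of them leaving out 1 array (adjusted p up to 0.303). The endoplasmic reticulum list was not called: 10 of 60 rose and 22 fell (10 and 22 adjusted over the list alone), at a median of -0.14 (0.02 centred), a sign that changed with the centring (camera adjusted p = 0.3).

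**Figure D3:**
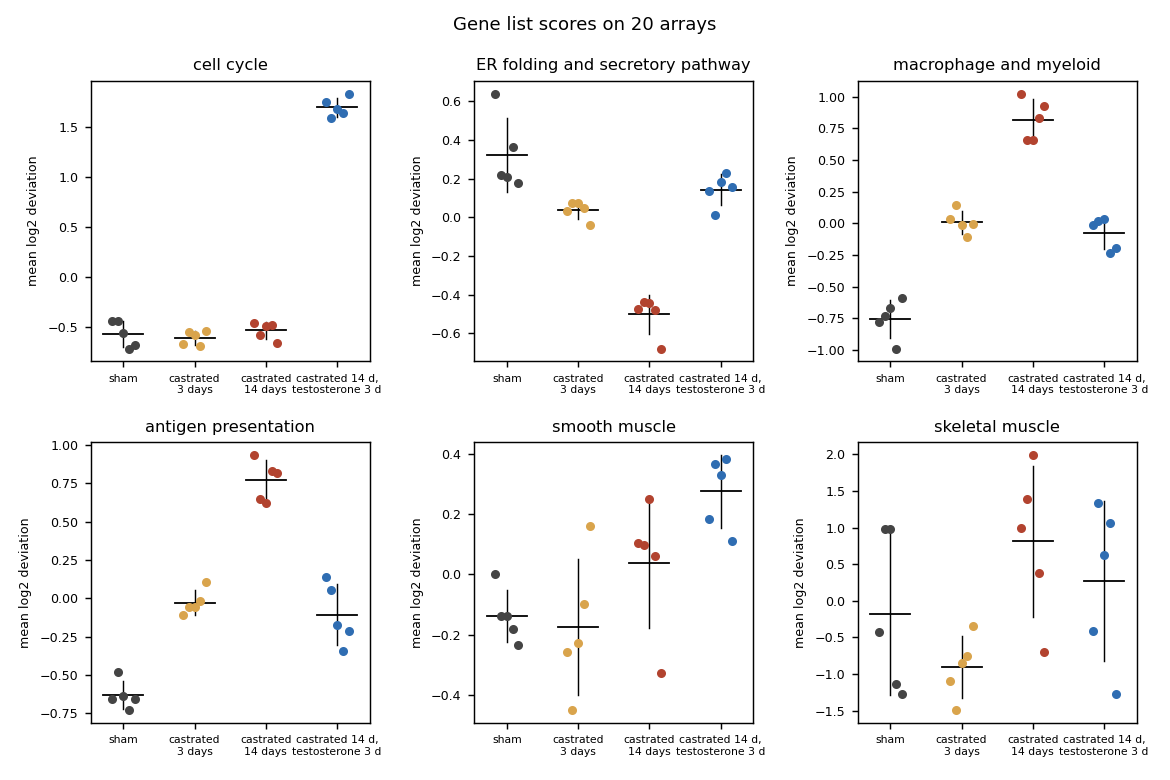
Score of 6 gene lists on 20 arrays by group, a score being the mean over a list's genes of the log2 signal minus the gene's mean over all arrays, with points for arrays, horizontal lines for means and vertical lines for SD. Cell cycle scores separated the testosterone group from the other 3 groups, and skeletal muscle scores varied within groups with an SD of 0.956.

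Calls of both castration times were compared for overlap. Of the 988 probe sets called at 3 days, 834 (84.4%) were called in the same direction at 14 days, 580 higher and 254 lower, against 195 and 74.8 for independent lists. Igfbp3, Dbp, Cadps, Cdh13 and Clu rose and Msmb, Ptgs2 and Fkbp5 fell at both times. Both comparisons share the sham arrays: the correlation of log2 changes across probe sets was 0.600 and the covariance 0.176, against 0.0238 for unchanged groups sharing the same arrays, a difference of 0.152. The simulated mean correlation was 0.490 over 100 simulations. With the sham arrays split in 3 and 2, 60.1% to 90.0% of the early calls were shared over 20 splits.

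Of the 3659 probe sets called between castration for 14 days and sham, 1639 (44.8%) were called in the opposite direction by testosterone, against 833 for independent lists, namely 1038 of 1980 that had risen and 601 of 1679 that had fallen. With each array centred on its median 1512 were opposed, and testosterone called 1827 probe sets higher and 1024 lower. The split by direction therefore depends on the scaling. Calls against sham, used below, also turned (2026 higher and 1206 lower when centred). Msmb, Fcgbp, Pbsn and Fkbp5 were among those that fell and rose again, and Igfbp3, Cdh13, Cadps and Car8 among those that rose and fell again. Here the castrated arrays are shared and the correlation of log2 changes across probe sets was -0.563 and the covariance -0.302, against -0.0212 for unchanged groups sharing the same arrays, a difference of -0.281. The simulated mean correlation was -0.464 over 100 simulations, and with the castrated arrays split 32.5% to 48.4% were opposed. Against sham, 2041 (55.8%) were still called on the castrated side after testosterone, 980 higher, Clu among them, and 1061 lower, Pbsn, Egf and Ptgs2 among them, against 961 for independent lists. Of these 2041, 409 had moved back, 1341 were not called between testosterone and castration, and 291 had moved further away from sham. A further 236 (6.45%) were called on the other side of sham, Fkbp5 among them, against 979. For this pair the correlation of log2 changes across probe sets was 0.558 and the covariance 0.298, against 0.0256 for unchanged groups sharing the same arrays, a difference of 0.272, the simulated mean correlation was 0.506 over 100 simulations, and with the sham arrays split 40.2% to 50.9% were still called on the castrated side and 2.21% to 10.4% beyond sham. 994 probe sets (27.2%) moved back and were no longer called against sham, which does not show that they equalled it.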

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

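Tests on arrays with loss of 5' signal in the comparison of castration for 14 days with sham, on the cell shares and on skeletal muscle were chosen after the results were seen, as were the 2 added settings.

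The testosterone comparison includes 4 arrays of high Gapdh 3' to 5' ratio, 2 in each group. Loss of 5' RNA on these arrays as the whole source of the change would leave signs on them unrelated to the other 6 arrays, but of 2646 probe sets called on the 6 arrays 2435 (92.0%) had the same sign on the 4. Of the 3099 calls made with all arrays, 2273 (73.3%) were kept without the 4, as were 2779 of 3665 (75.8%) for testosterone against sham. In the comparison of castration for 14 days with sham, 2784 of 3659 calls (76.1%) were kept without the 2 castrated arrays concerned. Without all 4 arrays 3002 (82.0%) of these were kept, more than without 2, and the testosterone arrays also enter the spread shared by all groups. For the calls not kept in these comparisons, loss of 5' RNA, loss of power with fewer arrays and a changed estimate of the spread cannot be told apart. Each of the 5 counts was the highest among 100 of 126 splits of its 10 arrays (1 of 100 in each case), the smallest share that 100 splits can give. Such splits cannot tell the treatment from anything else that differs between the groups. The real counts and the highest of the other splits were 988 and 20 for castration for 3 days against sham, 3659 and 1284 for 14 days against sham, 2802 and 95 for 14 against 3 days, 3099 and 1284 for testosterone against castration, and 3665 and 2003 for testosterone against sham; of the splits drawn, 4 kept the 4 arrays together in the testosterone comparison and called at most 621.

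Macrophage, antigen presentation and fibroblast genes were higher after 14 days of castration. A smaller epithelial share alone would raise markers of every other cell type alike, but the macrophage score rose by 1.40 more than the smooth muscle score (SD within groups 0.266), the antigen presentation score by 1.23 (0.224) and the fibroblast score by 0.534 (0.154), each with an exact permutation p of 0.00794, the smallest that 5 against 5 arrays can give. Smooth muscle was the only reference list, and 8 of its 20 genes rose while 5 fell. The fibroblast score itself rose by 0.71, less than the endothelial and nerve scores, so its result depends on the reference and decides nothing. Antigen presentation genes are not markers of a single cell type, so the prediction does not strictly apply to them. The luminal score differed by -0.0359 (exact p = 0.286), the smooth muscle score by 0.176 (exact p = 0.127), the basal score by 0.372, the endothelial score by 0.787 and the nerve score by 0.971. More cells of these types and higher expression per cell remain open, since whole tissue was measured.

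Skeletal muscle genes were higher at 14 than at 3 days of castration. Striated muscle carried over at dissection in amounts that differ between mice may be the source: the SD of the score within groups was 7.95 times the median over the other 28 lists (0.956 against 0.120, the highest other being 0.678). Of the 54 genes of the list 30 were measured, 2 of which are also in another list, and Acta1 measured 4776 ± 2183 in sham, 909.9 ± 413 after 3 days, 3202 ± 1976 after 14 days and 11498 ± 2171 with testosterone (SD, n = 5). In that last group Acta1 ran from 9518 to 14705 while Cox6a2 ran from 30.6 to 1258, so Acta1 does not vary there as the carried-over tissue would need. The score was 1.72 higher than at 3 days (exact permutation p = 0.0159) and 0.989 higher than in sham (exact permutation p = 0.19), so an effect of castration time cannot be told apart from carried-over tissue with 5 mice per group.

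The castration effect at 14 days differed from that at 3 days for 2802 probe sets, by the direct test between both castrated groups. Some single arrays lay far from the other 4 of their group, judged by the gap to the nearest array over the whole range, a rule that picks about 1 group in 20 by chance. Among 116 groups of list scores, where chance gives about 5.8, 6 were picked: androgen-responsive genes (-0.145 on castrated 14 days replicate 5), androgen-responsive genes (0.170 on testosterone replicate 4), castration-induced regression genes (0.288 on castrated 3 days replicate 5), castration-induced regression genes (-0.220 on testosterone replicate 5), endoplasmic reticulum folding and secretory pathway (-0.680 on castrated 14 days replicate 5) and cadherins and catenins (0.320 on castrated 3 days replicate 5). None of 12 groups of array measures was picked, but the rule looks for a single array. It cannot pick arrays that lie far out together, as those of high Gapdh 3' to 5' ratio did in the castrated 14 days and testosterone groups. Among 792 groups of signals of genes named in the text, where chance gives about 39.6, 52 were picked.

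On sham replicate 1 the signals were Aldh1a1 4850.5, Col3a1 1074, Creld2 12261, Cxcl12 662, Lcn2 1437, Manf 8850.5, P4hb 1902, Pbsn 14179.6, Pdia4 3355 and Sprr1a 358. On sham replicate 2 the signal was Csf3r 1012. On sham replicate 4 the signals were Adipoq 138, B2m 17264, Car3 85.5, Cd53 15.9, H2-DMb1 137 and Wfdc2 38.9. On castrated 3 days replicate 1 the signal was Mki67 12.0. On castrated 3 days replicate 2 the signals were Col3a1 1948, Srm 948 and Xbp1 3853. On castrated 3 days replicate 4 the signals were Bak1 361, Fgf1 676, H2-DMb1 333, Myog 181 and P4hb 1579.7. On castrated 3 days replicate 5 the signals were Actg2 2971, Cav1 3819, Gjb2 405, Mfge8 2747, Sat1 3403, Sbp 8478, Uqcrq 3919.6 and Wfdc2 43.9. On castrated 14 days replicate 1 the signal was Dbp 734. On castrated 14 days replicate 3 the signals were Cyba 1794, Itga7 329 and Myh9 1685. On castrated 14 days replicate 4 the signal was Canx 626. On castrated 14 days replicate 5 the signals were Abca1 2970.5, Bmp7 194, Cdk1 29.3, Cldn5 360.3, Igfbp2 258, Lcn2 244, Notch4 67.5, Svs2 151 and Tcf19 23.3. On testosterone replicate 1 the signal was Pbsn 7814. On testosterone replicate 2 the signals were Mgst1 1460.1 and Prph 7.30. On testosterone replicate 5 the signal was Cadps 122.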

How the results depend on the processing

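Fits without the 4 arrays of high Gapdh ratio and with the skeletal muscle score as a covariate were chosen after the results were seen. No paired analysis was possible because the labels pair no mice across groups. The 5 counts of changed probe sets and the 3 overlaps stayed within 1.5 times their value under the alternatives, apart from the threshold of 0.01, which left 465 for castration for 3 days against sham and 1755 for 14 against 3 days by its construction. Leaving out 1 array gave 727 to 1061 for 3 days against sham, 3290 to 3782 for 14 days against sham, 2348 to 2969 for 14 against 3 days, 2792 to 3139 for testosterone against castration and 3245 to 3695 for testosterone against sham. It gave 1435 to 1750 opposed calls, 1788 to 2081 calls still different from sham and 626 to 882 shared early and late calls. In place of 57 list calls, 53 to 60 were made with 1 array left out, 2 with an estimated correlation, 98 with fry for one direction and 131 with fry for either direction; fry asks whether a list's genes change and does not compare them with other genes. Apart from these other list tests, 37 list calls were kept in all 33 settings run on lists at the threshold of 0.05. Of 641 calls of single genes named by the rule or in the text, 531 were kept under every alternative that tested them at 0.05 and 110 were lost in at least 1. The direction reversed for 2 results, both with the skeletal muscle score as a covariate and for 14 against 3 days: camera's direction for the skeletal muscle list turned to lower, with a median log2 change of 0.10, as that covariate is the list's own score, and the log2 change of Pip became -0.10, the cause of which was not tested. The fit without the 4 arrays of high Gapdh ratio left 70 single-gene results untested, a filter on the mean 68 and leaving out 1 array up to 26, since genes above the filter on few arrays then failed it; Mki67, Top2a and Cdh13 were among these. Genes whose signals lie near the background on every array were not tested.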

Other observations

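The test of recovery below was fixed before its result was seen. Epithelial gene lists were not called in any comparison. After 14 days of castration 12 of 38 rose and 8 fell (12 and 8 adjusted over the list alone) in the luminal list (camera adjusted p = 0.978 by limma's camera): Agr2 (-2.86), Spdef (-1.49) and Ehf (-1.30), genes of secretory cells, fell. With testosterone 5 of 38 rose and 16 fell (5 and 18 adjusted over the list alone), as Agr2 (2.69) rose while the claudin gene Cldn4 (-1.49) and Lgals4 (-1.14) fell (camera adjusted p = 0.128). Of basal genes, 12 of 22 rose and 4 fell (13 and 4 adjusted over the list alone) after 14 days, with Col17a1 (1.86), Sfn (1.41) and Krt6a (1.24) higher and Gjb2 (-1.49) lower (camera adjusted p = 0.0943). Krt6a (-1.78) and Col17a1 (-1.01) fell with testosterone. Urothelial genes such as Sprr1a (0.76 after castration and -1.64 with testosterone) gave camera adjusted p-values of 0.469 and 0.246. Of the androgen-responsive genes, 5 of 18 rose and 8 fell (5 and 8 adjusted over the list alone) after 14 days, and the median was 0.00404 (camera adjusted p = 0.544). Aldh1a3, an enzyme of retinoic acid synthesis, rose after castration (1.96) and fell with testosterone (-2.09), opposite to Fkbp5.

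Adipocyte genes were not called as a list (camera adjusted p = 0.162 after 14 days and 0.136 with testosterone): 7 of 15 rose and 2 fell (8 and 2 adjusted over the list alone) after 14 days, and 1 of 15 rose and 7 fell (1 and 7 adjusted over the list alone) with testosterone. Among them Retn (2.99 and -3.18), Adipoq (2.02 and -2.78) and Lpl (1.45 and -1.48) rose and then fell. The score of this list, which also holds Car3, ran from -0.66 to 0.14 within sham. Whether these transcripts came from prostate cells was not tested. In the glutathione and antioxidant list 14 of 42 rose and 17 fell (14 and 17 adjusted over the list alone) after 14 days (camera adjusted p = 0.526). The metallothioneins Mt1 (-2.41) and Mt2 (-2.17) fell while the transferases Gstt1 (2.39) and Mgst1 (2.29) rose. Mt1 (1.66), Mt2 (1.76) and the dehydrogenase gene Aldh1a1 (2.00) rose with testosterone (camera adjusted p = 0.0576). Among blood genes, all 6 measured changed after 14 days, 4 higher, including Hbb-b2 (1.52) and Hba-a1 (1.13), and 2 lower, including Bpgm (-1.89). These counts were 4 and 2 adjusted over the list alone, at a camera adjusted p of 0.491. Between the testosterone group and sham, 1388 of the 3665 probe sets called had not been called after 14 days of castration, 550 higher and 838 lower.

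A hypothesis was that genes responding early to castration recover further under testosterone. Recovery was the share of the castration change reversed by testosterone, over probe sets changed at least 2-fold by 14 days. Its median was 0.616 over 382 probe sets already called at 3 days, such as Msmb and Igfbp3, and 0.437 over 561 not called then, such as Fcgbp and Egf. The difference was 0.180 (95% bootstrap interval over arrays 0.0132 to 0.287) and reached 0.1 in 77.2% of draws, short of the 95% fixed in advance, so the hypothesis stays open. Among probe sets that fell, the medians were 0.693 (99 early) and 0.384 (269 late), and among those that rose 0.606 (283 early) and 0.594 (292 late). The early and late sets thus held different shares of falls, and the difference within each direction was not tested.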
